A study of Pimephales promelas with 24 samples.

How the data were processed

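One table of the whole series was analysed. It holds 24 columns, 1 per fish, and 15744 spots of a one-colour (Cy3) Agilent array, of which 15208 are fathead minnow probes (14498 with AF and 710 with AM in their names) and 536 are control spots. Per the labels' protocols, total RNA of the ovary was extracted on columns, labelled with the manufacturer's one-colour kit and hybridised. The submitters' processing notes name Agilent Feature Extraction 9.5. No other step is given in the sources used here.

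The deposited values are scores without a stated unit. Every column has a median of 1 over all spots and values between approximately 0.7 and 2.3. The authors thus appear to have divided the log signal of each spot by the median log signal of its array, a step that no label records. The scale is not stated and was estimated under an assumption. On some arrays several spots (up to 32) share the highest value, as saturated spots would, while on 11 of the 24 arrays 1 spot holds it. If the highest value of each array is a full 16-bit signal (a log2 of 16), a score unit is worth 6.89 to 7.44 log2 units, with a mean of 7.13. As a check, low values were searched for even steps of signal, allowing 1 or 2 steps per signal unit. The 3 arrays with the clearest steps, picked for that reason, gave 6.91 to 7.14 log2 units. The other 21 arrays had weaker steps, and their best matches spread from 5.94 to 8.60. The highest were those of the 4 arrays of trenbolone alone (TRB, 8.31 to 8.60), followed by 8.18 in control replicate 4. Such units would put the highest value of these arrays above a full 16-bit signal. The mean factor of 7.13 was used for each log2 and fold value of a probe, which are approximate for that reason. A common factor changes no p-value. The design was written for log2 values; the same limma test was kept for these scores.

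The table pairs no probe with a gene, and none of the identifiers occurs in the gene table given for the species (assembly fPimPro1.hap1.1), so 0 probes have gene names. The gene list tests, the correlation of an aromatase transcript with estradiol release and the choice of 1 probe per gene were therefore not run. Named probes follow a rule fixed before the data were examined: where no gene names exist, the 2 identifiers with the largest rise and the 2 with the largest fall among probes past the threshold.

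Groups were taken from sample titles. limma 3.58.1 in R 4.3.3 fitted 1 coefficient per group to all 24 arrays, without covariates or a filter on dim probes, and moderated the variances with eBayes. Contrasts were TRB, MIX, TCC5 and TCC1 against control, MIX against TRB, MIX against TCC5, TCC5 against TCC1, the interaction, both main effects of the 2 by 2 part and a moderated F-test over the 5 groups. Probes with a Benjamini-Hochberg adjusted p under 0.05 over the 15208 probes of a contrast were counted. The fit was tested on simulated data with 200 changed probes per fold size and normal noise drawn independently for each probe. Depth in counts does not apply to arrays; their number limits the precision. Negative control spots (77 per array) gave the background level, as their 95th percentile on each array. A probe not above it on any array of a group has only a bound there: the bright group's mean was set against the mean of, per array, the higher of this percentile and the probe's own value.

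Body measurements of each fish stand in the labels. Differences of group means (of log10 values for vitellogenin) were tested with two-sided exact permutation tests, in which the smaller tail is doubled, in Python 3.11.15 with scipy 1.17.1, with Benjamini-Hochberg adjustment over 39 tests (6 measurements and 7 comparisons, leaving out 3 comparisons in which each tubercle score was 0). Plasma estradiol had values for 1 control, 5 TCC1, 0 TCC5, 1 TRB and 2 MIX fish and was not tested. The gonadosomatic index of 1 TRB fish was left out because the labels give none.

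Fixed before the data were examined were the groups, tests, named-probe rule and these alternatives: quantile normalization, centring on array medians, filters on dim probes (the dimmest 25% or 50%), fits to the compared groups alone, array weights, eBayes with trend and robust settings, the tank number, the title number or the sampling day as a block, leaving out the 3 fish noted as ovulating, other thresholds (adjusted p under 0.1, or at least 1.5-fold), a per-probe test with unequal variances, leaving out each array in turn, and log10 values or medians for body measurements. Added after seeing the data were an array-specific scale from the highest value, cyclic loess, a common median absolute deviation, the interquartile range as a covariate, probes above the negative controls on every array, each sampling day alone, and an exact test that counts absolute differences. That last version was the first one run on the body measurements; the version with a doubled tail, as scipy computes it, then became the reported one. The plan had named a two-sided exact permutation test without fixing how the tails are combined, and results of both versions are given. Other splits of the arrays (100 per comparison) were drawn with a fixed seed.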

Results

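Ovaries of 24 adult female fathead minnows (Pimephales promelas, a small cyprinid fish used in aquatic toxicology) were profiled, 1 array per fish, after 22 days of continuous exposure through the water. The exposures were triclocarban, an antimicrobial compound of soaps, 17β-trenbolone, a synthetic androgen used as a growth promoter in cattle, and their mixture. The groups were clean lake water (control, 5 fish), triclocarban at 1 µg/L (TCC1, 5 fish), triclocarban at 5 µg/L (TCC5, 5 fish), trenbolone at 0.5 µg/L (TRB, 4 fish) and triclocarban at 5 µg/L with trenbolone at 0.5 µg/L (MIX, 5 fish). Within a group each fish came from a tank of its own. Fish were sampled on 2 days, with 3 fish of each group on day 1 and 2 on day 2, except that 1 TRB fish was sampled on day 2. The labels of each fish also give plasma vitellogenin, plasma testosterone, nuptial tubercle score, gonadosomatic index (ovary weight as a percentage of body weight) and the estradiol and testosterone that pieces of its ovary released ex vivo in 12 h.

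Each array measured 15208 fathead minnow probes. Values are scores centred near 1, so that a difference of 0.1 between groups corresponds to approximately 0.71 on the log2 scale. All log2 and fold values given for probes are approximate in this sense. Arrays of the same group correlated with r between 0.944 and 0.984 over 46 pairs, and arrays of different groups with r between 0.928 and 0.984 over 230 pairs. These correlations are across probes, which are not independent replicates. The share of probes above the 95th percentile of the negative control spots was 90.1% ± 4.86 (SD, n = 5) in control, 90.6% ± 6.09 (n = 5) in TCC1, 92.1% ± 5.21 (n = 5) in TCC5, 94.6% ± 5.13 (n = 4) in TRB and 89.5% ± 8.51 (n = 5) in MIX. The number of arrays limited the precision: the 95% confidence interval of a group difference had a median half-width of 0.39 to 0.42 on the log2 scale. Probe identifiers carry no gene names here, so transcripts are described by number, direction, brightness and a few identifiers.

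The question of the trenbolone exposure is what a potent androgen does to females under these conditions, and it also gives the reference for the mixture. Females exposed to trenbolone alone had less circulating vitellogenin than controls (single fish from 0.0037 to 2.36 mg/ml). Vitellogenin is the egg yolk precursor that the liver makes under estrogen. Their plasma held 0.979 ± 0.994 mg/ml (SD, n = 4) against 22.0 ± 6.83 mg/ml (n = 5) in control females, and the geometric means differed 78.6-fold (18.9-fold without TRB replicate 2 and 162-fold without TRB replicate 4). All 4 carried nuptial tubercles, a male secondary sex character of this species, with a score of 12.5 ± 3.32 against 0 in all 5 controls. Their ovaries released 0.0594 ± 0.0214 ng/ml of estradiol in 12 h against 0.308 ± 0.122 in controls, which is 5.18-fold less, while testosterone release was 0.276 ± 0.152 against 0.317 ± 0.122 ng/ml. Plasma testosterone was 1.76 ± 0.524 ng/ml against 7.13 ± 1.66 ng/ml. The gonadosomatic index was 19.2% ± 6.86 in the 3 TRB fish with a value and 12.9% ± 1.30 in the 5 controls.

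No TRB fish overlapped the control range in vitellogenin, tubercle score, plasma testosterone or ex vivo estradiol. Each of these 4 differences had a two-sided exact permutation p of 0.0159, the smallest that a doubled tail can give with 4 against 5 fish, and an adjusted p of 0.0619 over the 39 tests of body measurements. Gonadosomatic index (exact p = 0.179, 3 against 5 fish) and ex vivo testosterone (exact p = 0.714, 4 against 5 fish) did not pass the test. Over all comparisons 13 of the 39 differences had an unadjusted p under 0.05, where chance gives 1.95, and 0 had an adjusted p under 0.05. A version of the exact test that counts absolute differences, and so does not double a tail, gave 8 of the 39 an adjusted p of 0.0387; both versions were run and the doubled one is reported throughout. Split by sampling day, these 13 differences gave 26 within-day values in the pooled direction. In 9 of the 13 the ranges of the groups do not overlap, so that this direction was given beforehand, and day 2 holds 1 TRB fish.

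**Figure D1:**
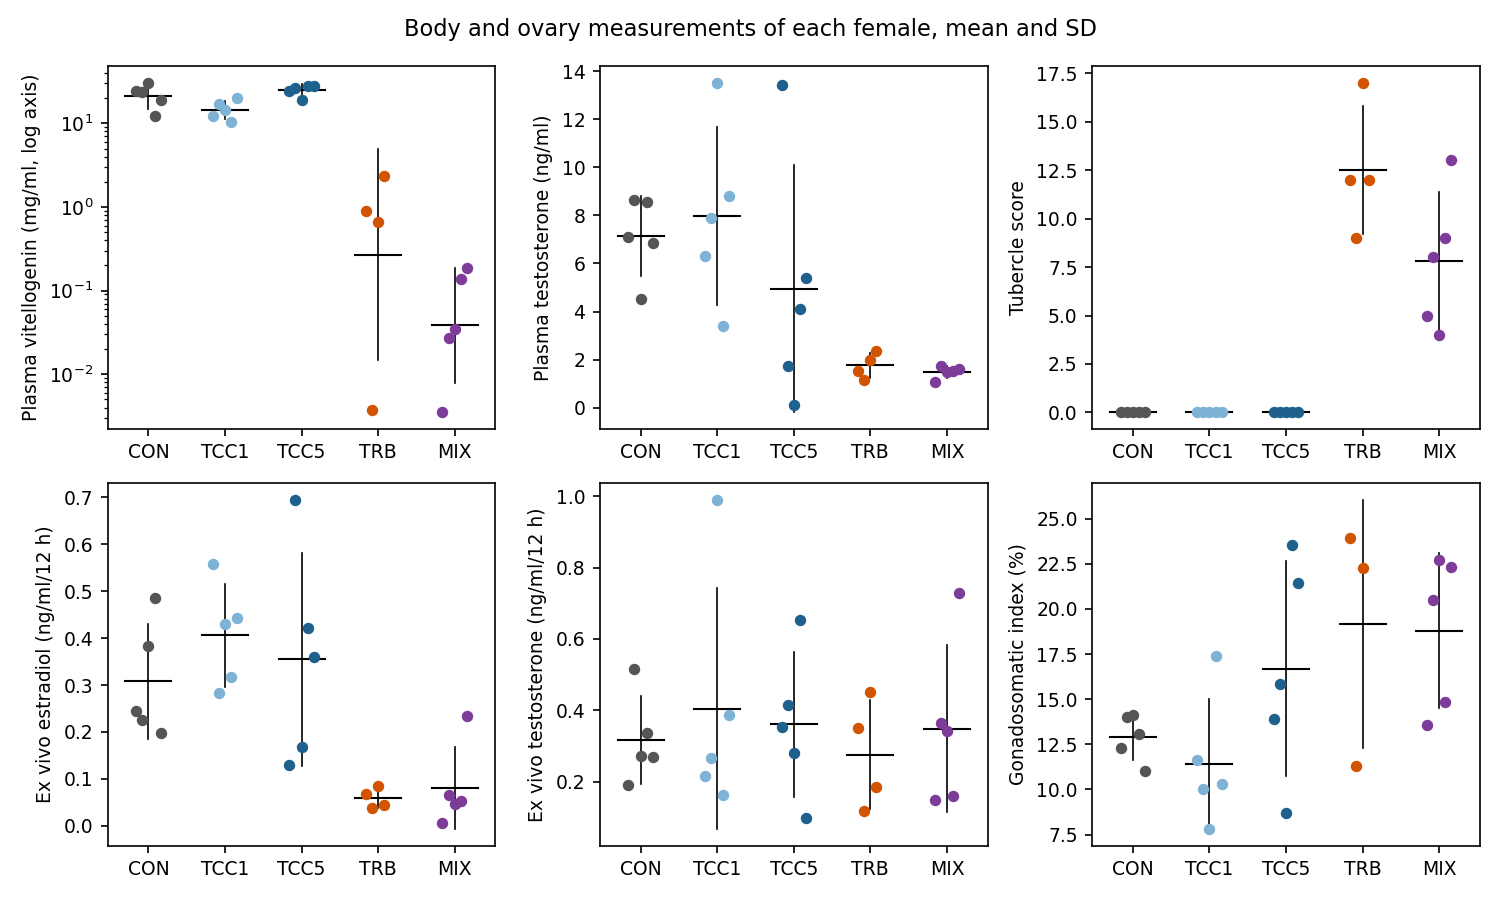
Plasma vitellogenin (mg/ml, log axis), plasma testosterone (ng/ml), tubercle score, ex vivo estradiol and testosterone (ng/ml in 12 h) and gonadosomatic index (%) of each fish by group, with horizontal lines at means (geometric for vitellogenin) and vertical lines for 1 SD. TRB and MIX fish have vitellogenin between 0.0035 and 2.36 mg/ml, all below the 10.3 to 30.4 mg/ml of the other groups, and they are the only groups with tubercle scores above 0.

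In the ovary, trenbolone alone was compared with control over all probes. Of the 15208 probes 3241 (21.3%) differed between TRB and control in limma (adjusted p under 0.05), with 1290 higher and 1951 lower. The balance was 61 and 1871 without the dimmest 50% of probes and turned to 759 higher and 460 lower with the interquartile range of the array as a covariate, under which 41.6% of the 3241 kept their sign. That range was higher on the control arrays (0.476 to 0.494) than on all others, and lower on the TRB arrays (0.370 to 0.406). Fits with this covariate, here and in other comparisons with control or TRB, thus cannot separate the spread from the group. The direction followed brightness. In the brightest 3802 probes 1553 fell and 0 rose, and in the dimmest 3802 probes 503 rose and 3 fell. The median change was 0.51 on the log2 scale among the probes that rose and -0.74 among those that fell, and 44 and 224 of them changed at least 2-fold. Of the 1951 that fell, 1931 lay above the negative controls on all 24 arrays, and of the 1290 that rose 303 did.

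The largest falls were those of UF_Ppr_AF_115272, with a log2 change of -6.09 ± 1.67 (SE; limma adjusted p = 0.0182), and UF_Ppr_AF_115478, with -5.90 ± 1.38 (limma adjusted p = 0.00969). Control fish were spread widely, with replicates 2, 3 and 5 high: UF_Ppr_AF_115478 had a score of 0.837 ± 0.0371 (SD, n = 4) in TRB and 1.66 ± 0.510 (n = 5) in control, and UF_Ppr_AF_115272 had 0.929 ± 0.0797 and 1.78 ± 0.576. Their scores were also below the control mean without trenbolone, at 0.977 ± 0.121 and 1.20 ± 0.210 in TCC1 (n = 5) and 1.19 ± 0.419 and 1.28 ± 0.514 in TCC5 (n = 5). In TRB fish UF_Ppr_AF_115478 scored 0.792 to 0.881, just above the 95th percentile of the negative control spots on the same arrays (0.785 to 0.875). The size of its fall is thus limited by the background. The largest rises were 1.68 ± 0.59 for UF_Ppr_AF_117212 (limma adjusted p = 0.0472) and 1.31 ± 0.47 for UF_Ppr_AF_115893 (limma adjusted p = 0.0492). None of these 4 calls held after quantile normalization (limma adjusted p from 0.206 to 0.210), although the differences in score went only from 0.236 to 0.261 for UF_Ppr_AF_117212, 0.183 to 0.224 for UF_Ppr_AF_115893, -0.854 to -0.838 for UF_Ppr_AF_115272 and -0.828 to -0.806 for UF_Ppr_AF_115478. Without the ovulating fish the call of UF_Ppr_AF_115478 alone held, while the differences of the others were 0.267 (UF_Ppr_AF_117212), 0.207 (UF_Ppr_AF_115893) and -0.802 (UF_Ppr_AF_115272). That of UF_Ppr_AF_117212 also ended with array weights (limma adjusted p = 0.0644). Leaving out 1 array ended it for control replicates 1 to 5 and TRB replicates 2 and 3 (limma adjusted p up to 0.182), of UF_Ppr_AF_115893 for control replicates 1 to 4 and TRB replicates 2 and 3 (up to 0.199) and of UF_Ppr_AF_115272 for TRB replicate 2 (0.0649).

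As a measured fact beside these counts, bright probes lay closer to the array median in TRB than in any other group. The 75th percentile of the probes was 1.281 ± 0.0224 (SD, n = 4) in TRB and 1.358 ± 0.00474 (n = 5) in control, with all 4 TRB arrays below the other 20 (two-sided exact permutation p = 0.0159 against control). It was 1.351 ± 0.00945 (n = 5) in MIX, 1.336 ± 0.0119 (n = 5) in TCC1 and 1.337 ± 0.0149 (n = 5) in TCC5, both also below control (exact permutation p = 0.00794 each, 5 against 5 arrays). Below the median TRB did not stand apart, with a 25th percentile of 0.895 ± 0.00806 (n = 4) in TRB, 0.899 ± 0.00450 (n = 5) in TCC5 and 0.873 ± 0.00867 (n = 5) in control. Control arrays stood apart at the other end: their interquartile range was 0.476 to 0.494, above that of every other array (at most 0.473, in MIX). After quantile normalization, which gives all arrays the same distribution, 0 probes passed and 2181 had an unadjusted p under 0.05, where chance gives 760. Among the 3241 probes the median absolute change went from 0.67 to 0.25 on the log2 scale, the median SE from 0.18 to 0.18, and 88.9% kept their sign. The count also went from 3241 to 589 without TRB replicate 2, to 2081 without control replicate 2, to 1901 without control replicate 3 and to 1666 without the ovulating fish; within sampling day 1 it was 1480 (3 against 3 fish), day 2 holds 1 TRB fish and says nothing about it, and 12 probes passed a per-probe test with unequal variances.

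**Figure D2:**
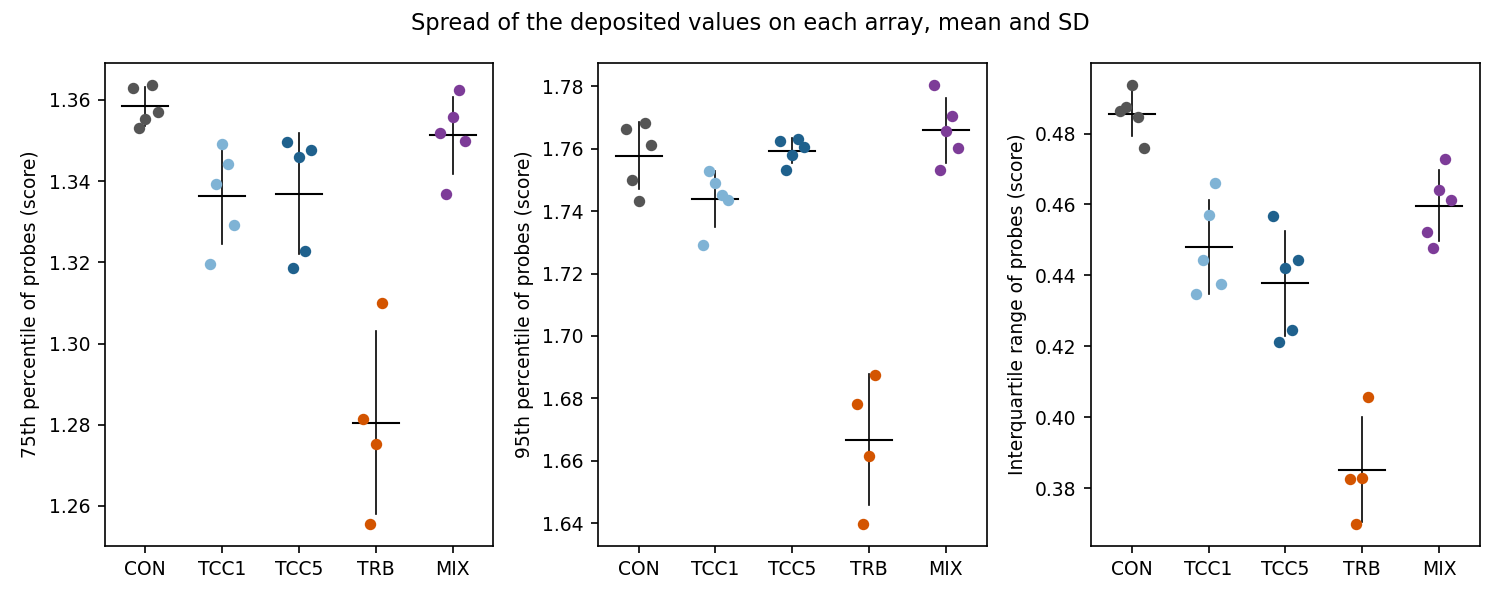
The 75th percentile, the 95th percentile and the interquartile range of the probe scores on each array by group, with horizontal lines at means and vertical lines for 1 SD. The 4 TRB arrays lie between 1.26 and 1.31 in the 75th percentile, below the 20 other arrays, whose lowest value is 1.319.

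**Figure D3:**
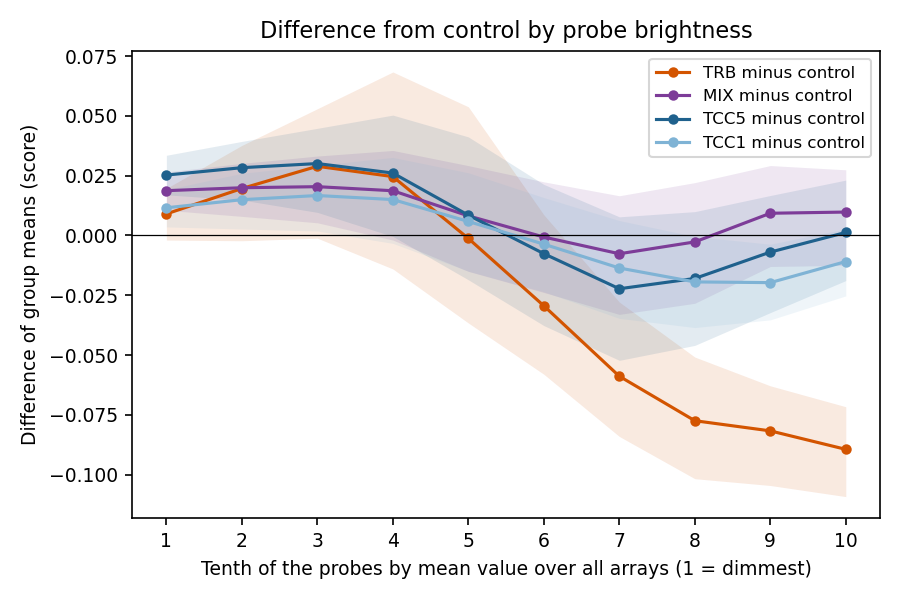
Median difference from control in score (lines) and its interquartile range over probes (bands), in 10 equal bins of probes from dimmest to brightest, for TRB, MIX, TCC5 and TCC1. The TRB line runs from 0.00900 in the dimmest bin to -0.0894 in the brightest, while MIX runs from 0.0187 to 0.00978, TCC5 from 0.0252 to 0.00126 and TCC1 from 0.0116 to -0.0109.

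The mixture answers whether triclocarban alters the response to the androgen. Fish given the mixture, like those given trenbolone alone, had low vitellogenin and carried tubercles. MIX females had 0.0781 ± 0.0798 mg/ml of vitellogenin (SD, n = 5), a geometric mean 546-fold below control (300-fold without MIX replicate 1), tubercle scores of 7.8 ± 3.56, plasma testosterone of 1.48 ± 0.259 ng/ml and ex vivo estradiol of 0.0810 ± 0.0879 ng/ml, which is 3.80-fold below control (7.16-fold without MIX replicate 5). Their gonadosomatic index was 18.8% ± 4.29 (n = 5), against 12.9% ± 1.30 in controls. Against control, vitellogenin, tubercle score and plasma testosterone each had an exact permutation p of 0.00794, the smallest that 5 against 5 fish can give, and an adjusted p of 0.0619. Gonadosomatic index and ex vivo estradiol each had an exact permutation p of 0.0238 and an adjusted p of 0.0714. Ex vivo testosterone, at 0.349 ± 0.235 ng/ml, did not differ from control (exact permutation p = 0.810, 5 against 5 fish).

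In the ovarian transcripts of MIX fish against control, 0 probes passed in limma and 1389 had an unadjusted p under 0.05, where chance gives 760. This does not show that they were alike: UF_Ppr_AF_115478 had a score of 0.881 ± 0.0503 (SD, n = 5) and UF_Ppr_AF_115272 one of 0.963 ± 0.122 in MIX, near those of TRB, without passing (limma adjusted p = 0.521 for both). With the interquartile range of the array as a covariate 97 probes passed. That range did not overlap between MIX (0.448 to 0.473) and control (0.476 to 0.494), so the 97 decide nothing. The per-probe test with unequal variances also gave 0 calls. Both exposures to trenbolone share the control arrays, and their differences from control correlated with r = 0.551 across probes. Simulated unchanged groups gave a mean of 0.465 (middle 95% of 1000 simulations, 0.128 to 0.749). With separate control fish for each comparison r averaged 0.225 over 10 splits of the controls. The covariance was 0.00148, within the middle 95% of simulations (0.000153 to 0.00156).

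MIX set directly against TRB asks what triclocarban at 5 µg/L added to the androgen. In the ovary, 1634 probes differed in limma, of which 1591 were higher in MIX and 43 lower, and 1443 of the higher ones were in the brightest 3802 probes. The median rise was 0.76 on the log2 scale. UF_Ppr_AF_100235 rose by 2.28 ± 0.64 (SE; limma adjusted p = 0.0270) and UF_Ppr_AF_114147 by 2.17 ± 0.60 (limma adjusted p = 0.0248). UF_Ppr_AF_100008 had a change of -0.91 ± 0.29 (limma adjusted p = 0.0441) and UF_Ppr_AF_116264 one of -0.86 ± 0.26 (limma adjusted p = 0.0373). Leaving out 1 array ended each call: for TRB replicates 1 or 2 or MIX replicates 1 or 5 (UF_Ppr_AF_100235), TRB replicates 1 or 3 or MIX replicates 2 or 3 (UF_Ppr_AF_114147), TRB replicates 1 or 4 or MIX replicates 1 to 5 (UF_Ppr_AF_100008), and TRB replicates 2 or 3 or MIX replicates 1 to 4 (UF_Ppr_AF_116264), with a limma adjusted p of up to 0.215. Without the ovulating fish those of UF_Ppr_AF_100235 (0.0633), UF_Ppr_AF_114147 (0.0591) and UF_Ppr_AF_100008 (0.132) ended, with differences in score of 0.315, 0.241 and -0.106 against 0.320, 0.304 and -0.127 in all fish, and with array weights that of UF_Ppr_AF_116264 (0.0645; all limma adjusted p). Of the probes lower in TRB than in control, 1160 were higher in MIX than in TRB, where independent lists would share 204. The shared TRB arrays by themselves turn these comparisons against each other, however (r = -0.779 across probes, and -0.491 with separate TRB arrays). Simulated unchanged groups gave a mean r of -0.553 (middle 95% of 1000 simulations, -0.789 to -0.214). The covariance of -0.00278 lay outside the middle 95% of simulations (-0.00175 to -0.000276), and was -0.00203 with separate TRB arrays.

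No body measurement separated MIX from TRB fish in the exact permutation test. Tubercle scores were 7.8 ± 3.56 (n = 5) and 12.5 ± 3.32 (n = 4), with an exact permutation p of 0.143, and log10 vitellogenin was -1.41 ± 0.687 and -0.572 ± 1.26, with an exact permutation p of 0.254. Ex vivo estradiol (exact p = 0.905, 5 against 4 fish) and plasma testosterone (exact p = 0.333, 5 against 4 fish) did not separate them either. With 5 against 4 fish this does not show that the groups were alike. The geometric mean of vitellogenin was 6.95-fold lower in MIX, 29.0-fold without TRB replicate 2 and 3.36-fold without TRB replicate 4. Only TRB replicate 2 (0.0037 mg/ml) lay within the MIX range of 0.0035 to 0.187 mg/ml. After quantile normalization 0 probes differed between MIX and TRB, with 1254 at an unadjusted p under 0.05, and with the interquartile range as a covariate 445 were higher and 312 lower, of which 10 were among the 1634. The count was 423 within sampling day 1 (3 against 3 fish), while day 2 holds 1 TRB fish and says nothing about it, and 89 by the per-probe test with unequal variances. Without TRB replicate 2 it was 495, without TRB replicate 3 it was 969, and without MIX replicate 1 it was 1086.

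For triclocarban alone, no body measurement passed the test against control, which with 5 against 5 fish does not show that they were alike. In TCC5 fish vitellogenin was 25.3 ± 3.94 mg/ml (SD, n = 5), plasma testosterone 4.95 ± 5.15 ng/ml (single fish from 0.129 to 13.4; 0.695 of control, and 0.398 without TCC5 replicate 1, an ovulating fish), ex vivo estradiol 0.355 ± 0.226 ng/ml, gonadosomatic index 16.7% ± 5.95 and the tubercle score 0 in all 5 fish. In TCC1 fish these were 14.8 ± 3.83 mg/ml, 7.99 ± 3.70 ng/ml, 0.406 ± 0.110 ng/ml, 11.4% ± 3.60 and 0 (n = 5). No difference of either group from control had an exact permutation p under 0.0952. Between both concentrations, log10 vitellogenin was 1.40 ± 0.0734 in TCC5 and 1.16 ± 0.113 in TCC1, a 1.73-fold difference of geometric means (exact permutation p = 0.0159, 5 against 5 fish; adjusted p = 0.0619).

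In the ovary, 0 probes passed in limma for TCC5 against control, with 2988 at an unadjusted p under 0.05 and a smallest adjusted p of 0.139, and 0 for TCC1 against control, with 908. TCC5 against TCC1 gave 0 probes, with 750 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0564. The per-probe test with unequal variances called 1 probe for TCC5 against control and 0 for the comparisons of TCC1 with control and of both concentrations. With array weights 677 probes passed for TCC5 against control, of which 562 were higher, and 51 passed with trend and robust settings. With the interquartile range as a covariate 1255 passed for TCC5 and 172 for TCC1 against control, but that range overlapped with control in neither group. Leaving out control replicate 1 gave 1 probe for TCC5 against control, leaving out TCC5 replicate 1 gave 2, and leaving out TCC1 replicate 4 gave 1 for TCC1 against control. In simulated data of this comparison, limma recovered 27.5% of probes changed 1.5-fold, 69% of those changed 2-fold and 88% of those changed 3-fold. The simulated noise was normal and independent between probes, without the differences in spread between the real arrays. These shares thus do not give the power in the real data.

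Pooling both settings in which triclocarban at 5 µg/L was added (control to TCC5, TRB to MIX) gave 217 probes in limma, and all 217 were higher with triclocarban, 210 of them in the brightest 3802 probes. Among bright probes both settings were not alike. In the brightest of 10 equal bins of probes the median difference in score from control was 0.00126 in TCC5, 0.00978 in MIX and -0.0894 in TRB. In the brightest 3802 probes 1443 rose from TRB to MIX, while 0 probes passed for TCC5 against control. The pooled count thus cannot be read as a rise shared by both settings. UF_Ppr_AF_107839 rose by 1.22 ± 0.27 on the log2 scale (SE; limma adjusted p = 0.0304). UF_Ppr_AF_117272 (limma adjusted p = 0.0256) was not above the negative controls in any of the 5 control or 4 TRB fish, and had a score of 1.22 ± 0.0553 (SD, n = 5) in TCC5. That placed TCC5 at least 6.79-fold above control, taking the 95th percentile of the negative control spots as the control level. In MIX it was above the negative controls in 3 of 5 fish, with a score of 1.01 ± 0.256 (SD, n = 5). Leaving out 1 array ended the call of UF_Ppr_AF_117272 for control replicates 2 and 3, TRB replicate 2 and MIX replicate 1, and of UF_Ppr_AF_107839 for control replicate 3, TRB replicates 1 and 2 and MIX replicate 1. The count of 217 went to 0 after quantile normalization (559 probes at an unadjusted p under 0.05) and without the ovulating fish (2236 at that p). It was also 0 with trend and robust settings (2787 at that p) and with the interquartile range as a covariate. The difference in score of UF_Ppr_AF_117272 went from 0.307 to 0.292 after quantile normalization and 0.311 without the ovulating fish. That of UF_Ppr_AF_107839 went from 0.172 to 0.143 and 0.163. Leaving out single arrays moved it to 3 (TRB replicate 2), 7 (MIX replicate 1), 13 and 28 (control replicates 3 and 2), 101, 122 and 374 (TRB replicates 3, 1 and 4), 106 (MIX replicate 3), and 103, 114 and 602 (TCC5 replicates 5, 3 and 4).

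Adding trenbolone to triclocarban (MIX against TCC5) went with lower vitellogenin and with tubercles in the fish, while no ovarian transcript passed the test. Vitellogenin was 648-fold lower by geometric mean (356-fold without MIX replicate 1) and the tubercle score 7.8 against 0, each with an exact permutation p of 0.00794 (5 against 5 fish; adjusted p = 0.0619). Ex vivo estradiol was 4.38-fold lower, and 8.26-fold without MIX replicate 5 (exact permutation p = 0.0238, 5 against 5 fish; adjusted p = 0.0714). In limma 0 probes passed, 607 had an unadjusted p under 0.05, and the per-probe test with unequal variances called 0; leaving out TCC5 replicate 1 gave 1 probe. Pooled with TRB against control, the trenbolone effect had 43 probes in limma, all lower (353 higher and 342 lower with the interquartile range as a covariate), among them UF_Ppr_AF_103636 with a change of -0.89 ± 0.19 (SE; limma adjusted p = 0.0468) and UF_Ppr_AF_100986 with -0.82 ± 0.17 (limma adjusted p = 0.0476). This count was 0 after quantile normalization (878 probes at an unadjusted p under 0.05) and 0 without any single one of control replicates 4 and 5, TRB replicate 2, MIX replicates 2, 3 and 4 and TCC5 replicate 1 (1587 to 2553 at that p). It was also 0 without the ovulating fish (1757 at that p), with trend and robust settings (2286) and without the dimmest 25% of probes (1933). Without the ovulating fish the calls of UF_Ppr_AF_103636 and UF_Ppr_AF_100986 ended (limma adjusted p = 0.0807 and 0.0804). Their differences in score were then -0.130 and -0.136, against -0.124 and -0.115 in all fish. Leaving out 1 array ended the call of UF_Ppr_AF_103636 for 13 of 19 arrays and of UF_Ppr_AF_100986 for 14. The count was 12 to 18 without control replicate 3, TRB replicates 1 or 3, MIX replicate 5 or TCC5 replicates 3 or 5, and 69 to 143 without control replicates 1 or 2, TRB replicate 4 or TCC5 replicates 2 or 4.

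Whether the mixture departs from the sum of its parts was tested as the difference between the triclocarban effect with and without trenbolone. The test used the deposited scores, not log2 values. On this scale 1552 probes departed from additivity in limma, a count that was far lower with an array-specific factor to log2 units. Of the 1552 probes, 897 lay above the sum and 655 below. The balance turned with the interquartile range as a covariate (408 above, 736 below) and with trend and robust settings (672 and 763), and without the dimmest 50% of probes it was 537 and 5. Among the 897, 732 were in the brightest 3802 probes, and among the 655, 265 were in the dimmest 3802 probes and 376 in the next 3802. UF_Ppr_AF_109737 exceeded the sum by 3.40 ± 1.01 (SE; limma adjusted p = 0.0402) and UF_Ppr_AF_114147 by 3.18 ± 0.83 (limma adjusted p = 0.0301). UF_Ppr_AF_104962 had an interaction of -2.77 ± 0.64 (limma adjusted p = 0.0245) and UF_Ppr_AF_116213 one of -1.46 ± 0.47 (limma adjusted p = 0.0494). In the order control, TCC5, TRB and MIX, mean scores were 1.53, 1.37, 1.16 and 1.48 for UF_Ppr_AF_109737. They were 2.05, 1.91, 1.81 and 2.11 for UF_Ppr_AF_114147, 0.961, 1.24, 0.996 and 0.888 for UF_Ppr_AF_104962, and 0.923, 1.02, 1.07 and 0.970 for UF_Ppr_AF_116213. In both probes above the sum, each single exposure was thus lower than control and MIX was near control. Leaving out 1 array ended the call of UF_Ppr_AF_109737 for 13 of 19 arrays, of UF_Ppr_AF_116213 for 14, of UF_Ppr_AF_114147 for TRB replicates 2 and 3 and of UF_Ppr_AF_104962 for TRB replicate 2. Without the ovulating fish the call of UF_Ppr_AF_109737 alone ended (limma adjusted p = 0.0506), with a difference in score of 0.514 against 0.477 in all fish. A test for any difference among the 5 groups called 874 probes, and far fewer with an array-specific factor. The interaction went to 0 after quantile normalization (1857 probes at an unadjusted p under 0.05), to 14 without TRB replicate 2 and to 0 within sampling day 1 (3092 probes at an unadjusted p under 0.05), and the 874 went to 0 (1021 at that p) with quantile normalization and to 7 without TRB replicate 2. Quantile normalization took the differences in score from 0.477 to 0.405 (UF_Ppr_AF_109737), 0.446 to 0.331 (UF_Ppr_AF_114147), -0.389 to -0.405 (UF_Ppr_AF_104962) and -0.205 to -0.226 (UF_Ppr_AF_116213). Without single other arrays the interaction count was 570 and 614 (control replicates 2 and 3), 792 (TRB replicate 3), 738, 675 and 663 (MIX replicates 3, 4 and 5), and 2756, 548, 680 and 847 (TCC5 replicates 1, 2, 3 and 4), and the 874 became 343 and 273 (TRB replicates 1 and 3), 581 (TCC1 replicate 2) and 1339 (TCC5 replicate 4).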

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

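The splits of the arrays, the tests of the TRB arrays' spread, of the set of probes around UF_Ppr_AF_115478 and of UF_Ppr_AF_117272 in MIX fish were chosen or read after the results were seen; for the shuffles of on and off probes the reading was set before their share was seen, but the minimum gap of 0.2 was set after probes of this kind had been looked at by group.

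The difference between TRB and control was tested against the difference between MIX and TCC5 in the deposited scores. This interaction called 1552 probes, a count that quantile normalization took to 0 (1857 at an unadjusted p under 0.05). The count was also far lower with an array-specific factor. The pair farthest above the sum was UF_Ppr_AF_109737 (3.40 on the log2 scale) and UF_Ppr_AF_114147 (3.18), and the pair farthest below it UF_Ppr_AF_104962 (-2.77) and UF_Ppr_AF_116213 (-1.46). In 100 splits of the same arrays 1 gave as many probes as the 1552, the real split itself, and the highest of the others gave 509. With 100 splits no share below 1 of 100 can be found, and they were read after the counts were seen. The labels of all groups in the interaction were shuffled together, which tests any difference among them and not additivity itself. The real split also gave the most probes for TRB against control (1 of 100 splits, 3241 probes, highest other 615) and MIX against TRB (1 of 100, 1634, highest other 101). So it did for any difference among groups (1 of 100, 874, highest other 470).

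For the pooled trenbolone effect 2 of 100 splits gave as many as the 43 probes, with 387 in the highest other, and for the pooled triclocarban effect 2 of 100 gave as many as the 217, with 1895 in the highest other. Where limma called 0 probes, 100 of 100 splits necessarily gave as many, which says nothing about chance. The highest other was 2 for MIX against control (1389 probes at an unadjusted p under 0.05, 0 by the per-probe test with unequal variances), 1708 for TCC5 against control (2988 and 1), 18 for TCC1 against control (908 and 0), 2 for MIX against TCC5 (607 and 0) and 1 for TCC5 against TCC1 (750 and 0). The splits with 387 and 1895 probes, several times the real 43 and 217, and the one with 1708 where the real split gave 0, may point to a structure of the samples other than the groups; this was not tested further.

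The first pattern is that bright probes lay closer to the array median on the TRB arrays than in any other group, while dim probes did not stand apart there. Trenbolone at this concentration irrespective of triclocarban is argued against, since the 75th percentile of MIX differed from control by -0.0071 (SE 0.00473) and that of TRB by -0.0779; an effect of trenbolone that triclocarban offsets stays open. A flatter response of these arrays could shrink the span of a pair of spike-in controls, and the span exceeded the one predicted from each array's probes by 0.0502 more in TRB than in control (SE 0.0447, exact permutation p = 0.254, 4 against 5 arrays), which leaves it open; that pair was picked after all control spots had been viewed. A labelling, slide or normalization step shared by the TRB arrays cannot be told apart from the exposure, because all 4 TRB arrays lay below the other 20 and no slide or labelling batch is given. In the search for signal steps the 4 TRB arrays also had the highest log2 units per score (8.31 to 8.60). A larger unit would by itself bring bright probes closer to the median, but these weak steps cannot decide it. The control arrays stood apart as well, with an interquartile range above that of all others. TRB against control thus sets the narrowest group against the widest.

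The second pattern is that UF_Ppr_AF_115478, 1 of the pair of probes with the largest falls in TRB, varied among fish together with other probes. In the 15 fish without trenbolone, 33 probes formed a set correlated with it at r over 0.9, a minimum chosen after several had been tried. The 33 include the probe itself and UF_Ppr_AF_115272. As many were found in 4 of 1000 shuffles within groups, although the shuffled counts lack the sure match of the probe with itself. A state of the ovary that moves the whole set may account for its level and stays open. Of the 9 fish given trenbolone, 3 lay over 2 residual SD below the line of the probe on the mean of the 31 other members, and 9 of 9 lay below it. The set was picked for its correlation in the fish that fit the line and the probe for its fall in TRB, so these values decide nothing. Tissue of another kind in some samples cannot be told apart, because the 33 probes have no gene names.

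The third pattern is that UF_Ppr_AF_117272 was above the gap between its low and high values in 5 of 5 TCC5 fish, 1 of 5 TCC1 fish, 0 of 5 controls and 0 of 4 TRB fish. Probes that are on or off between fish irrespective of exposure are a candidate explanation: of 49 probes with such a gap 1 parted an exposed group from the controls, and 12.7% of 10000 shuffles of the labels did as well. Triclocarban at 5 µg/L irrespective of trenbolone stays open, with 2 of 5 MIX fish above the gap (Fisher's exact p = 0.167 for TCC5 against MIX). No biological explanation was tested beyond the exposures.

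Single fish or arrays far from the others of their group came to 13 in 121 groups of values, where chance gives 6.05. Among body measurements these were ex vivo estradiol of MIX replicate 5 (0.233 ng/ml, others 0.00706 to 0.0651) and ex vivo testosterone of TCC1 replicate 3 (0.990 ng/ml, others 0.163 to 0.387). The span of the spike-in controls was 0.624 in TCC5 replicate 2 (others 0.698 to 0.727). Scores of single probes were 0.986 for UF_Ppr_AF_115893 in MIX replicate 4, 1.18 for UF_Ppr_AF_115272 in MIX replicate 5, 1.92 for UF_Ppr_AF_115478 in TCC5 replicate 4 and 1.25 for UF_Ppr_AF_100235 in control replicate 3. Others were 0.907 for UF_Ppr_AF_116264 and 1.78 for UF_Ppr_AF_103636 in TCC5 replicate 1, and 1.51 for UF_Ppr_AF_103636 in MIX replicate 4. The last were 1.21 for UF_Ppr_AF_117272 in TCC1 replicate 4, 1.33 for UF_Ppr_AF_107839 in TCC1 replicate 5 and 1.25 for UF_Ppr_AF_104962 in control replicate 1.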

How the results depend on the processing

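The sampling days taken alone, an array-specific factor, cyclic loess, a common median absolute deviation, the interquartile range as covariate, the filter on negative controls and the count of absolute differences were chosen after seeing the data; the other alternatives were fixed before. Body measurements kept direction and side of the threshold in 424 of the fixed alternatives and reversed in 25, and in the added ones they did in 87, reversed in 10 and passed in 8. Counts of probes stayed within 1.5 times in 189 fixed and 37 added alternatives and moved beyond it in 109 and 40. Named probes kept their call in 235 fixed and 32 added alternatives, lost it in 143 and 71 and reversed in 4 added. Signal over background limits dim probes: 303 of the 1290 probes that rose in TRB lay above the negative controls on all arrays. Gene list tests, the aromatase correlation and the choice of 1 probe per gene were not run for want of gene names. Except where fewer probes or arrays or a changed threshold account for it, the cause was not tested.

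Counts under each alternative are given in limma unless stated. Quantile normalization gave 0 for TRB against control, MIX against TRB, the interaction, both main effects and any group difference (2181, 1254, 1857, 878, 559 and 1021 at an unadjusted p under 0.05), and cyclic loess gave 0 for the same (2425, 1132, 1901, 949, 513 and 1003). Under quantile normalization the changes among the 3241 probes shrank from 0.67 to 0.25 on the log2 scale while the SE stayed at 0.18. Centring on medians gave 10 for the trenbolone main effect. Without the dimmest 25% of probes TCC5 against TCC1 had 1 and the trenbolone main effect 0; without the dimmest 50% TRB against control had 1932, the interaction 542 and the trenbolone main effect 0. Array weights gave 677 for TCC5 against control, 1 for TCC1 against control, MIX against TCC5 and TCC5 against TCC1, 2739 for the interaction, 73 and 683 for the trenbolone and triclocarban main effects and 1729 for any difference. Trend and robust settings gave 672 above and 763 below for the interaction, 51 for TCC5 against control, 1 for TCC5 against TCC1 and 0 for both main effects. Fish with the same tank number showed no steady pairing (17 of 46 pairs with r over 0.1, 0 of 10 group pairs throughout), which cannot exclude one. As a block tank numbers gave 27 for the trenbolone main effect, title numbers 135 and sampling day 91, with 1 for TCC5 against TCC1 by day. Tanks 1 to 3 were sampled on day 1 and tanks 4 and 5 on day 2, so the tank and day blocks are not separate checks. Without the ovulating fish TRB against control had 1666, TCC5 against control and MIX against TCC5 1, both main effects 0 and any difference 316.

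An adjusted p under 0.1 gave 5002 for TRB against control, 2663 for MIX against TRB, 1 for TCC5 against TCC1, 3467 for the interaction, 342 and 589 for the main effects and 2073 for any difference. A change of at least 1.5-fold left 2120 for TRB against control, 18 and 49 for the main effects. Fits to the compared groups alone gave 1332 for TRB against control, 1 for TCC5 against control, MIX against TCC5 and TCC5 against TCC1, 953 for the interaction and 2 and 44 for the main effects. The per-probe test with unequal variances gave 12 for TRB against control, 1 for TCC5 against control and 89 for MIX against TRB. An array-specific factor gave 2430 for TRB against control (1215 higher, 1215 lower), 200 for MIX against TRB, 252 for the interaction, 0 for both main effects and 3 for any difference. A common median absolute deviation gave 0 for the trenbolone main effect. The interquartile range, taken next as a covariate, is confounded with group, since that of control and that of TRB overlapped with no other group. The interquartile range as covariate gave 1219 for TRB against control (9 shared with the 3241), 97 for MIX, 1255 for TCC5 and 172 for TCC1 against control, 757 for MIX against TRB (445 higher, 312 lower, 10 shared with the 1634), 1144 for the interaction (408 above, 736 below), 2 for MIX against TCC5, 695 and 0 for the main effects and 31 for any difference; it reversed UF_Ppr_AF_115893 (-0.424), UF_Ppr_AF_116264 (0.0763) and UF_Ppr_AF_116213 (0.417), in score. Probes above the negative controls gave 2096 for TRB against control and 700 for the interaction. Day 1 alone gave 1480 for TRB against control, 423 for MIX against TRB, 1 for TCC1 against control, TCC5 against TCC1 and any difference, and 0 for the interaction and main effects. Day 2 alone, with 1 TRB fish assumed to vary like the others, gave 0 for TRB against control, MIX against TRB and the main effects, 2 for the interaction and 1 for TCC5 against control, TCC1 against control, MIX against TCC5 and any difference, and reversed UF_Ppr_AF_115893 (-0.0290).

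Leaving out 1 array at a time, counts ranged from 589 to 3544 for TRB against control, 495 to 2150 for MIX against TRB, 14 to 2756 for the interaction, 0 to 143 and 3 to 602 for the trenbolone and triclocarban main effects, 7 to 1339 for any difference, 0 to 2 for TCC5 against control, and 0 to 1 for TCC1 against control and MIX against TCC5. For body measurements with a reversal the ranges were -0.0164 to 0.0401 (MIX against TRB), -0.137 to 0.00464 (TCC5 against TCC1) and -0.0380 to 0.103 (TCC5 against control) for ex vivo estradiol. For ex vivo testosterone they were -0.107 to 0.0618 (MIX against TCC5), -0.0223 to 0.131 (MIX against TRB), -0.0632 to 0.0820 (MIX against control), -0.0588 to 0.148 (TCC1 against control), -0.118 to 0.102 (TCC5 against TCC1), -0.0302 to 0.109 (TCC5 against control) and -0.0993 to 0.0115 (TRB against control). They were -4.33 to 1.99 for gonadosomatic index (MIX against TRB) and -0.527 to 2.00 for plasma testosterone (TCC1 against control).

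Other reversals of body measurements, none past the threshold, were on the log10 scale 0.00385 (gonadosomatic index, MIX against TRB), -0.0676 (ex vivo estradiol, MIX against TRB) and -0.0110 (ex vivo testosterone, MIX against control), and without the ovulating fish 1.99 (gonadosomatic index, MIX against TRB) and 0.00464 (ex vivo estradiol, TCC5 against TCC1). On day 1 they were -0.0478 (vitellogenin), -0.0655 (ex vivo estradiol) and -0.0820 (ex vivo testosterone) for TCC5 against control, 2.42 for gonadosomatic index of MIX against TRB and 0.174 for ex vivo testosterone of MIX against TCC5. On day 2 they were 0.0825 (vitellogenin, TCC1 against control), -1.55 (gonadosomatic index, MIX against TCC5), -0.0586 (ex vivo testosterone, MIX against control) and, for TCC5 against TCC1, 0.194 (ex vivo estradiol) and 0.208 (ex vivo testosterone). Counting absolute differences in the exact permutation test, run before the version with a doubled tail, passed 8 at an adjusted p of 0.0387: vitellogenin in TRB (-1.90) and MIX (-2.74) against control and MIX against TCC5 (-2.81), plasma testosterone in MIX (-5.65), tubercle score in TRB (12.5) and MIX (7.8) against control and MIX against TCC5 (7.8), and ex vivo estradiol in TRB (-0.248).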

Other observations

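All tests in this part were chosen after the values were seen.

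Estradiol and testosterone released by the same ovaries give a measure that the comparisons do not use, estradiol per testosterone. Its mean was 1.06 ± 0.450 (SD, n = 5) in control, 1.43 ± 0.840 (n = 5) in TCC1, 1.39 ± 1.38 (n = 5) in TCC5, 0.239 ± 0.0649 (n = 4) in TRB and 0.203 ± 0.122 (n = 5) in MIX. The hypothesis that trenbolone lowers the estradiol made per testosterone was tested by exact permutation on the log10 scale over 7 comparisons. The geometric mean of TRB was 0.241 of that of control (4 against 5 fish, exact p = 0.0159, adjusted p = 0.0370), that of MIX 0.171 of control (exact p = 0.00794, adjusted p = 0.0278) and that of MIX 0.170 of TCC5 (exact p = 0.00794, adjusted p = 0.0278). TCC5 over control was 1.01 (exact p = 0.984). Within sampling days 1 and 2 TRB over control was 0.267 and 0.189, and MIX over control 0.288 and 0.0787.

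A second hypothesis is that under trenbolone the estradiol made follows the testosterone made. Over the 9 fish given trenbolone r was 0.910 (exact permutation p = 0.000576, adjusted p = 0.00346 over 6 relations) and Spearman's rho 0.917 (exact permutation p = 0.00131), with r = 0.798 without the 2 fish farthest in testosterone. Within sampling day 1 r was 0.929 (6 fish), and day 2 held 3 such fish, too few for a value. Over the 15 other fish r was 0.194 (permutation p = 0.490, adjusted p = 0.734) and rho 0.20 (permutation p = 0.475); whether both correlations differ was not tested.

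The share of the ovary taken by large oocytes might set the spread of an array, in which case the gonadosomatic index would go with the 75th percentile. Over the 15 fish without trenbolone r was -0.239 (permutation p = 0.397, adjusted p = 0.734), rho -0.114 (permutation p = 0.686), and r -0.0375 without the 2 fish farthest in the index, so this stays open. Over the 8 fish with trenbolone that have an index r was 0.135 (exact permutation p = 0.738) and rho 0.0238 (exact permutation p = 0.977), and r -0.595 without the 2 farthest. Within sampling days this relation was not computed.

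Plasma estradiol was 3.45 ng/ml in the 1 control fish with a value, 2.93 ± 1.84 ng/ml (SD, n = 5) in TCC1, 0.595 ng/ml in 1 TRB fish, and 0.437 and 0.667 ng/ml in 2 MIX fish.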
